A study of Mus musculus with 9 samples.

How the data were processed

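RNA-seq of total RNA from MIN6 cells was analysed in 9 libraries, 3 each of untransfected control cells, cells overexpressing Nr4a1 and cells given EGCG upon Nr4a1 overexpression. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a stranded total RNA kit. All libraries carry the label batch 1. The dose and time of EGCG and the transfection method are not given in the sources used here. Groups and replicate numbers come from the sample titles.

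The deposited table gives TPM per Ensembl transcript for each of the 9 libraries, and every library sums to the same total. Per the submitters' processing notes, the authors used bcl2fastq 2.20, FastQC 0.11.9, cutadapt 2.8, STAR 2.7.1a and RSEM 1.2.31 and the GRCm39 build; the annotation release, the strand setting and any filter are not given in the sources used here. TPM divides each transcript's estimated reads by its length and by the library's sum, so a rise of abundant RNAs lowers the TPM of all others, and no depth can be recovered from it. Reads from near-identical copies, such as histone and small RNA genes, were shared out by the authors' estimation.

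Transcript identifiers were joined to genes with the GENCODE M21 annotation, which describes an older build and was used for names, biotypes, gene membership, and, within that build, for gene lengths and for which genes lie inside others. No coordinates are printed. Of 142435 identifiers, 138346 (97.13%) matched, giving 52408 genes; the 4089 unmatched ones held between 17.993% and 20.572% of the TPM of a library and were tested separately. TPM was summed per gene. Genes with at least 1 TPM in at least 3 libraries were tested, 11950 in all and 10760 of them protein coding.

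Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend) on log2(TPM + 1), with all 9 libraries in a single fit, two-sided, and Benjamini-Hochberg adjustment at 0.05 within the comparison. The unit is not a count, so no count model was used. Errors of TPM are SD over 3 libraries, and errors of log2 fold changes are limma's SE. Sets were tested with limma's camera at a preset correlation of 0.01, adjusted over 87 tests (29 lists with at least 3 tested members in 3 comparisons). With an estimated correlation camera called 0 lists in each comparison; limma's fry, which asks whether a list's genes move on balance in a single direction, called 24, 21 and 10 lists, and its mixed form 28, 27 and 26.

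The 33 lists, the tests, most alternatives and the rule for the genes named were set before the data were examined. The genes named are Nr4a1; for overexpression against control and for EGCG against overexpression, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 TPM, groups that do not overlap and a symbol that is not a predicted gene or clone name; and for each list up to 4 called members with the smallest adjusted p. Where no member of a list was called, its members of highest TPM could be named. A ranking of protein-coding genes alone, the chemoreceptor genes, the satellite-like genes, small RNA genes, histone genes, Nr4a2, Nr4a3, Hif1a, Il13, Il5, Kif3a and Rad50 were chosen after values were seen, though the chemoreceptor genes before their own values were.

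The fits were tested on simulated data with the real genes, means and spreads and 200 genes changed in 5 draws. For overexpression against control 68.4% of genes changed by 0.5 on the log2 scale and 94.6% of those changed by 1 were recovered, with 4.11% of calls false, over 11950 genes. For EGCG against overexpression the shares were 68.6%, 94.0% and 4.10%. These draws had independent normal noise, the same spread in every group and no shift of the TPM scale. The real comparisons called far more genes, 7106 and 6330, so the shares may not hold for them. Unchanged groups that share the overexpression libraries were simulated 100 times to set the expected correlation and covariance of the first 2 comparisons, and opposite genes were counted in them. Alternatives covered the pseudocount, the filter on low values, median-ratio, quantile and restricted scalings, the samples in the fit, the variance trend, library weights, a replicate block, a fold minimum and leaving out each library. Nuclear protein-coding genes alone and subtraction of the chemoreceptor genes' mean TPM were added after the data were seen. Other steps used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.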

Results

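Total RNA from MIN6 cells, a mouse insulinoma line that makes insulin and is used as a model of pancreatic beta cells, was sequenced in 9 libraries. The groups were untransfected control cells, cells overexpressing the orphan nuclear receptor Nr4a1, and cells given EGCG (epigallocatechin gallate, a green tea catechin) upon Nr4a1 overexpression, with 3 libraries each. Values are TPM, a length-corrected share of the transcripts of a library, as the authors deposited them, summed here per gene. TPM keeps no record of depth, so the depth of the libraries is unknown and no counting intervals can be given. Small structured RNAs held 44.3% ± 0.809 of the TPM in control, 49.7% ± 0.359 with overexpression and 48.9% ± 0.877 with EGCG (SD, n = 3 each), and protein-coding genes of the nucleus held 21.5% ± 0.267, 22.8% ± 0.243 and 20.6% ± 0.261. Changes are differences of mean log2(TPM + 1), which understates the change of genes with low TPM. Nothing in the labels says that the triplicates were separate cultures, so the p-values measure the spread between these libraries.

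Nr4a1 itself was at 0.723 ± 0.0814 TPM in control (SD, n = 3), 138.7 ± 23.1 TPM with overexpression and 53.9 ± 7.35 TPM with overexpression and EGCG. Overexpression thus raised the transcript 192-fold by group means (log2 fold change 6.33 ± 0.125 SE; limma, Benjamini-Hochberg adjusted p = 1.23e-08). With EGCG it fell by 1.34 ± 0.125 (SE) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 3.71e-05), to 38.8% of the level in the overexpressing cells. It remained 74.5-fold above control (log2 fold change 4.99; limma, Benjamini-Hochberg adjusted p = 2.06e-07). The EGCG group therefore differed from the overexpression group in the amount of Nr4a1 as well as in the compound. The related receptors Nr4a2 and Nr4a3 stayed under 1 TPM by group mean and were not tested.

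**Figure D1:**
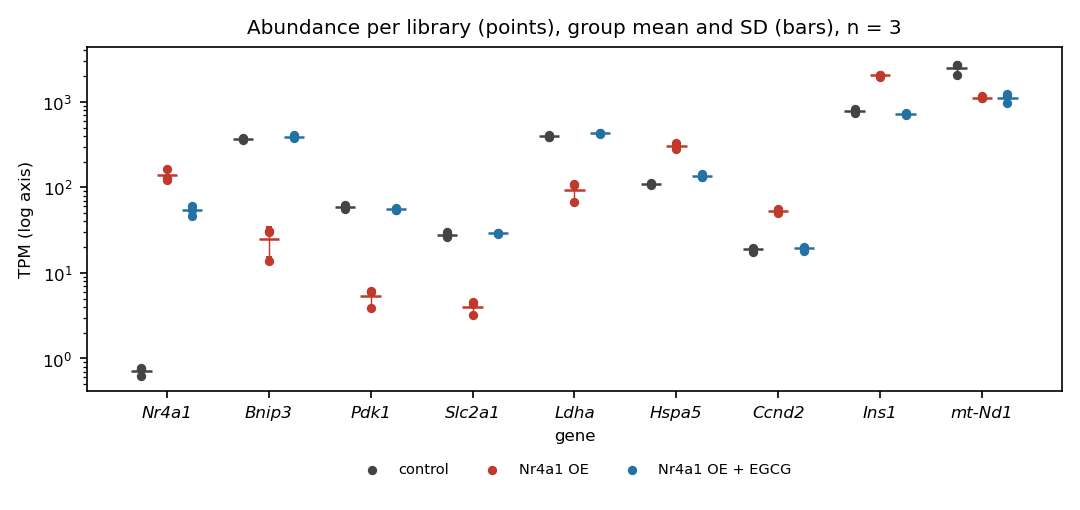
TPM on a log axis of 9 genes in each library (points) with group means and SD (bars, n = 3 per group) in control cells, Nr4a1-overexpressing cells and overexpressing cells given EGCG. Nr4a1 was at 0.723 TPM in control, 138.7 with overexpression and 53.9 with EGCG; Bnip3, Pdk1, Slc2a1 and Ldha were low with overexpression alone, Hspa5, Ccnd2 and Ins1 were high with overexpression alone, and mt-Nd1 was low in both transfected groups.

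The first comparison asked what Nr4a1 overexpression changed against untransfected control cells. Among the lists of known functions, hypoxia-inducible and glycolytic genes had the lowest medians. All 15 tested hypoxia-inducible genes were lower with overexpression, by a median of -2.54 on the log2 scale. Bnip3, a mitophagy receptor, dropped from 366.7 ± 8.17 to 24.9 ± 9.67 TPM (SD, n = 3 each), and Fam162a from 211.9 ± 13.5 to 23.3 ± 3.33 TPM. Pdk1, which restrains the use of pyruvate in mitochondria, was at 59.3 ± 2.55 TPM in control and 5.31 ± 1.2 TPM with overexpression, and Ankrd37 at 24.9 ± 0.616 and 1.79 ± 0.368 TPM. Of 19 glycolysis genes, 16 fell and 2 rose, with a median of -1.74. Among them were the glucose transporter Slc2a1 (28.1 ± 1.92 to 4.03 ± 0.722 TPM), which is also on the hypoxia list, the aldolase Aldoc (15.2 ± 0.953 to 1.34 ± 0.194 TPM), the enolase Eno2 (48.8 ± 1.93 to 9.68 ± 0.727 TPM) and the phosphofructokinase Pfkp (235.1 ± 7.0 to 69.6 ± 5.01 TPM). The lactate exporter Slc16a3 fell by 3.72 ± 0.419 (SE) and lactate dehydrogenase Ldha by 2.09 ± 0.154 on the log2 scale. The hypoxia list (camera, Benjamini-Hochberg adjusted p = 3.28e-15) and the glycolysis list (adjusted p = 4.80e-10) both stood apart from other genes with camera at its preset correlation, while with an estimated correlation the adjusted p was 0.269 for each. Adjusted over the list alone, 15 hypoxia genes and 18 glycolysis genes changed.

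Genes of the cell cycle, of protein folding in the endoplasmic reticulum, of the proteasome and of the respiratory chain rose with overexpression. Of 37 cell cycle genes, 31 rose and 1 fell, with a median log2 fold change of 0.47. Cyclin D2 (Ccnd2) rose from 18.8 ± 0.964 to 53 ± 3.11 TPM, Cdc20 from 15.5 ± 0.902 to 42.1 ± 1.78 TPM, and thymidylate synthase (Tyms) from 26.1 ± 0.947 to 62.9 ± 1.82 TPM (SD, n = 3 each). Of 28 genes for chaperones and the unfolded protein response, 22 rose and 1 fell (median 0.66), led by the chaperone Hspa5, which went from 109.7 ± 1.94 to 305.3 ± 24.1 TPM, and by Xbp1 and Dnajc3, with log2 fold changes of 1.01 and 1.12. Of 31 proteasome genes, 28 rose and none fell (median 0.41), among them Psmc4 at 35.6 ± 2.01 and 64.3 ± 0.276 TPM. Of 40 nuclear genes of oxidative phosphorylation, 29 rose and 4 fell (median 0.44), with Atp5a1 at 143.0 ± 5.25 and 266.6 ± 4.13 TPM. These 4 lists were called with camera at its preset correlation (Benjamini-Hochberg adjusted p = 7.10e-06, 7.05e-05, 7.91e-06 and 0.00211 in the same order), and with an estimated correlation their adjusted p was 0.296, 0.457, 0.296 and 0.667. Adjusted over the list alone, 32, 24, 28 and 33 members changed. With quantile normalization the medians of the 4 lists were 0.305, 0.529, 0.219 and 0.279. Of 26 integrated stress response genes 15 rose and 5 fell, 21 adjusted over the list alone, without a call of the list (camera, Benjamini-Hochberg adjusted p = 0.493).

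Beta cell genes moved in both directions. Ins1, which encodes insulin, rose from 784.9 ± 45.1 to 2030.0 ± 67.5 TPM (log2 fold change 1.37 ± 0.0679 SE), and the potassium channel subunit Kcnj11 and the incretin receptor Glp1r rose by 0.90 and 1.16 on the log2 scale. No value is given here for Ins2, the other insulin gene, so Ins1 does not stand for all insulin transcript. Of 36 genes of the insulin granule and secretion, 16 rose and 6 fell; the list's median of 0.11 turned to -0.02 with median-ratio scaling, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.813). Adjusted over the list alone, 25 changed. Of 15 beta cell transcription factors, 4 rose and 3 fell, with Pdx1 at 42.4 ± 2.56 TPM in control and 70.6 ± 4.03 TPM with overexpression, Mafa at 62.9 ± 5.17 and 38.7 ± 0.248 TPM, and Pax6 at 71.2 ± 10.7 and 45.4 ± 2.88 TPM (camera, Benjamini-Hochberg adjusted p = 0.873); 7 changed adjusted over the list alone. Glucagon (Gcg) rose from 322.8 ± 9.04 to 759.3 ± 42.7 TPM, and of the 6 tested genes of other islet hormones and their regulators 4 rose and 2 fell, and all 6 changed adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.413). Immediate early genes fell, with 10 of 15 lower and 1 higher (median -0.39; camera, Benjamini-Hochberg adjusted p = 7.05e-05, and adjusted p = 0.269 with an estimated correlation). Ier3 dropped from 11 ± 0.671 to 3.39 ± 0.215 TPM, Dusp1 from 12.2 ± 0.195 to 4.38 ± 0.325 TPM and Jun from 8.82 ± 0.892 to 3.54 ± 0.171 TPM, and 11 of these genes changed adjusted over the list alone.

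Mitochondrially encoded genes went the other way from the nuclear respiratory genes. Of 13, 8 fell and 2 rose with overexpression (median -0.77), with mt-Nd1 at 2482 ± 385 TPM in control and 1121 ± 32.9 TPM with overexpression, and mt-Co1 at 6532 ± 459 and 3133 ± 29.1 TPM (SD, n = 3 each). The list was called with camera at its preset correlation (Benjamini-Hochberg adjusted p = 0.00267; adjusted p = 0.569 with an estimated correlation, and 0.0578 with quantile normalization), and 11 genes changed adjusted over the list alone. Beside this, the control libraries carried more signal over the genes of chemoreceptors, which act in sensory neurons. The 1478 olfactory, vomeronasal and trace amine receptor genes, chosen after the higher low-level signal in control had been seen, summed to 107.7, 91.7 and 50.0 TPM in the control libraries, to between 4.22 and 4.71 TPM with overexpression and to between 7.85 and 11.8 TPM with EGCG. Satellite-like predicted genes were highest in control too, and Gm10800 averaged 3872 TPM in control, 97.4 with overexpression and 117.9 with EGCG. Small RNA genes, a group chosen after the data were seen, moved in the opposite sense where they passed the test: 64 of 147 rose, 4 fell and 79 did not pass with overexpression. With EGCG against overexpression 8 of them rose and 17 fell, and against control 39 were higher and 0 lower.

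Single genes with the greatest changes came from several functions. Besides those above, the lowest by the rule for named genes were Espn, which encodes an actin-bundling protein (20.8 ± 2.42 to 0.770 ± 0.0794 TPM), the mitochondrial adenylate kinase Ak4 (15.2 ± 0.447 to 0.40 ± 0.281 TPM), Mgarp, Sncb, Prelid2 and Asdurf, the last a short gene that shares its locus with another and is therefore uncertain. After Nr4a1, the highest were mostly small nucleolar and other short RNAs. Snora15 was at 2.52 ± 4.36 TPM in control and 39.7 ± 14.6 TPM with overexpression, Snora78 at 36.1 ± 17 and 307.7 ± 69.7 TPM, and a copy of Rmrp at 110.6 ± 41.3 and 1008 ± 52.6 TPM. Snora9 and Snora21 were also among them, though Snora21 was no longer called without replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0526) or replicate 2 (adjusted p = 0.0517) of the overexpression group. Snora5c, AF357399 and Rnu11 were listed at 0 in all 3 control libraries and averaged 23.8, 15.1 and 28.3 TPM with overexpression. The protein-coding gene in that set was the cytokine Il4, at 0.597 ± 0.293 TPM in control and 15.0 ± 1.56 TPM with overexpression. A ranking of protein-coding genes alone, added after the values were seen, continued with the fructose transporter Slc2a5 (log2 fold change 2.38 ± 0.103 SE), the potassium channel Kcnk16 (2.38 ± 0.0657), transthyretin (Ttr, 2.29 ± 0.0943), tissue plasminogen activator (Plat, 2.17 ± 0.101), Saa3, Gcsh, Spp1 and Wdr6.

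In all, 7106 of 11950 tested genes changed with overexpression (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05), 4561 of them higher and 2545 lower, and 321 rose and 243 fell by at least 2-fold. Each library of the overexpression group lay on the same side of all control libraries in 64.97% of the tested genes, where chance gives 10%. The split of directions depended on the scale: 3406 rose and 3688 fell with median-ratio scaling, which moved the median of all genes by -0.11 on the log2 scale, and 3559 rose and 3389 fell with quantile normalization. Rescaling without mitochondrial genes, small RNAs, Nr4a1 and the 10 most abundant genes kept it at 4373 to 2765. It was 3820 to 3474 on nuclear protein-coding genes alone, an alternative added after the data were seen. The control cells were untransfected, so transfection is part of this difference, and without the filter on low values 4597 genes rose and 7798 fell.

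The second comparison asked what EGCG changed in cells overexpressing Nr4a1. The hypoxia-inducible and glycolytic genes that were low with overexpression alone were higher with EGCG. All 15 hypoxia-inducible genes rose (median 2.51) and 16 of 19 glycolysis genes rose, with 2 lower (median 1.81). Bnip3 went from 24.9 ± 9.67 to 389.7 ± 18.3 TPM (SD, n = 3 each), Pdk1 from 5.31 ± 1.2 to 55.4 ± 1.10 TPM, Fam162a from 23.3 ± 3.33 to 200.9 ± 0.383 TPM, and Adm, which encodes the vasodilator peptide adrenomedullin, from 0.253 ± 0.0802 to 6.31 ± 0.526 TPM. Slc2a1 rose by 2.59 ± 0.0998 (SE), Eno2 by 2.45 ± 0.0721 and Slc16a3 by 3.89 ± 0.419 on the log2 scale. Both lists were called with camera at its preset correlation (Benjamini-Hochberg adjusted p = 1.11e-16 and 2.20e-11), with an adjusted p of 0.269 for each under an estimated correlation; 15 and 18 members changed adjusted over the list alone. Immediate early genes rose in 7 of 15 cases and fell in 2 (median 0.19; camera, Benjamini-Hochberg adjusted p = 0.0153, adjusted p = 0.269 with an estimated correlation). This call ended with quantile normalization (adjusted p = 0.0874) and on nuclear protein-coding genes alone (adjusted p = 0.0547), an alternative added after the data were seen. Ier3 was at 3.39 ± 0.215 and 13.5 ± 1.44 TPM, and 9 of these genes changed adjusted over the list alone.

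Cell cycle, chaperone, proteasome and respiratory chain genes fell with EGCG. Of 37 cell cycle genes, 30 fell and 2 rose (median -0.47), and Ccnd2 dropped from 53 ± 3.11 to 19.4 ± 1.03 TPM. Of 28 chaperone and unfolded protein response genes, 22 fell and 1 rose (median -0.53), with Hspa5 at 305.3 ± 24.1 and 136.7 ± 6.30 TPM. Proteasome genes fell in 29 of 31 cases and none rose (median -0.45). Nuclear genes of oxidative phosphorylation fell in 28 of 40 cases, with 1 higher (median -0.29), and integrated stress response genes in 16 of 26, with 4 higher (median -0.30); the amino acid transporter Slc7a5 fell from 78.6 ± 1.36 to 31.6 ± 4.36 TPM, while the stress gene Ddit4 rose from 14.0 ± 0.512 to 43.8 ± 1.69 TPM. The 5 lists were called with camera at its preset correlation (Benjamini-Hochberg adjusted p = 1.49e-06, 7.05e-05, 1.60e-06, 0.00103 and 0.0235), and with an estimated correlation the adjusted p was 0.269, 0.457, 0.296, 0.649 and 0.569. With quantile normalization the calls of the oxidative phosphorylation list (median -0.088, camera adjusted p = 0.128) and of the integrated stress response list (median -0.136, camera adjusted p = 0.200) ended. There the medians of the cell cycle, chaperone and proteasome lists were -0.291, -0.348 and -0.228. Adjusted over the list alone, 37, 23, 29, 30 and 21 members changed.

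Among islet hormone genes, Ins1 dropped from 2030.0 ± 67.5 to 724.4 ± 17.9 TPM and Gcg from 759.3 ± 42.7 to 304.4 ± 17.3 TPM (SD, n = 3 each). Pdx1 fell by 1.05 ± 0.0878 (SE), Nkx6-1 by 1.10 ± 0.107 and Nkx2-2 by 0.93 ± 0.109 on the log2 scale. Of 15 beta cell transcription factors 7 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 0.313), and 8 changed adjusted over the list alone. Their median was -0.20, but -0.09 with median-ratio scaling, -0.083 with quantile normalization and -0.09 after rescaling. Of 36 genes of the insulin granule and secretion, 15 fell and 6 rose (median -0.12, but 0.002 with quantile normalization and 0.006 after rescaling; camera, Benjamini-Hochberg adjusted p = 0.450), 21 adjusted over the list alone; the incretin receptor Gipr rose from 1.87 ± 0.260 to 5.78 ± 0.476 TPM. Of the 6 other islet hormone genes, 4 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 0.277), 5 adjusted over the list alone. Of 13 mitochondrially encoded genes 1 rose, mt-Co1 (3133 ± 29.1 to 4656 ± 399 TPM), and 2 fell. Their median was -0.07, while camera's direction was up (Benjamini-Hochberg adjusted p = 0.970) and the median was 0.05 with median-ratio scaling; 2 changed adjusted over the list alone. The greatest falls among the genes chosen by rule were in Il4 (15.0 ± 1.56 to 0.923 ± 0.205 TPM), Kcnk16 (log2 fold change -2.12), Slc2a5 (-2.08), the peptide hormone Cck (179.0 ± 17.4 to 45.2 ± 6.59 TPM), Ttr, Plat, Pcp4, Gcsh, the histone gene Hist2h2aa1 and the growth factor gene Csf1. Without the filter on low values Hist2h2aa1 was no longer called (limma, Benjamini-Hochberg adjusted p = 0.0626). The greatest rises, beyond those above, were in Ak4, Mgarp, Ankrd37, Prelid2, Espn and the small RNA Rnu11, which went from 28.3 ± 32.3 to 188.4 ± 39.9 TPM.

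EGCG changed 6330 of 11950 tested genes against overexpression alone (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05), 2250 higher and 4080 lower, and 194 rose and 170 fell by at least 2-fold. The groups did not overlap in 64.56% of genes, where chance gives 10%. The split was 3163 higher and 2941 lower with median-ratio scaling, 2816 and 3101 with quantile normalization, and 3255 and 2892 after rescaling without mitochondrial genes, small RNAs, Nr4a1 and the 10 most abundant genes, which moved the median of all genes by 0.11 on the log2 scale. On nuclear protein-coding genes alone, an alternative added after the data were seen, it was 3704 and 2696, with the median moved by 0.14. No group received EGCG without Nr4a1 overexpression, and Nr4a1 itself was lower with EGCG.

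Genes that differed with overexpression mostly differed in the opposite direction with EGCG. The same overexpression libraries stand in both comparisons, so a trait of theirs unlinked to EGCG would also give opposite calls. Of the 7106 genes called against control, 5122 were called in the opposite direction with EGCG and 40 in the same direction. With overexpression 3408 of the opposite genes were higher than both in control and with EGCG, among them Ins1, Hspa5 and Ccnd2. The other 1714 were lower than in both, among them Bnip3, Pdk1 and Slc2a1. Independent lists of these sizes would share 2036.4 genes in opposite directions and 1727.7 in the same direction. Simulated unchanged groups that shared the overexpression libraries gave at most 1 opposite gene in 100 draws. Those groups held no changed genes, so few calls could arise, and this count does not bound what the shared libraries add. Part of the excess of opposite genes may come from the shared overexpression libraries. How much was not measured, because 3 libraries cannot be split into parts of at least 2. The log2 fold changes of the 2 comparisons correlated across genes with r = -0.81, against -0.50 on average and -0.74 at the lowest in the simulated groups. Their covariance was -0.206, against -0.0169 in the simulated groups, a difference of -0.189. Against control, 5475 of the 7106 genes were not called in the EGCG group, 1443 were called in the same direction as before, and 188 in the other direction. Of the 564 genes that overexpression had changed by at least 2-fold, 476 were called in the opposite direction with EGCG, and 206 were still called on the same side of control.

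**Figure D2:**
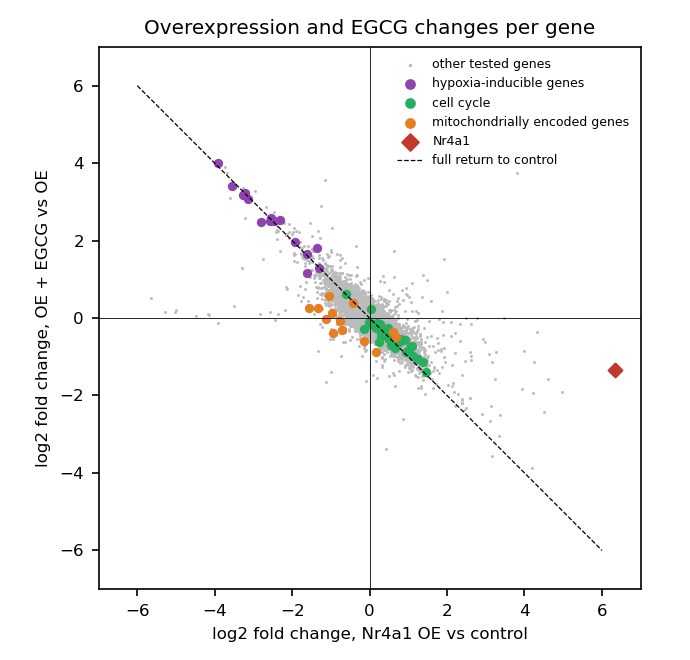
Log2 fold change of each of 11950 genes with EGCG against overexpression alone (vertical axis) by its log2 fold change with overexpression against control (horizontal axis); the dashed line marks full return to control. The 15 hypoxia-inducible genes lie along the line at its upper left, cell cycle genes lie near it at the lower right, most mitochondrially encoded genes lie off it near 0 on the vertical axis, and Nr4a1 lies at 6.33 and -1.34.

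The third comparison asked what still differed from control in cells with both Nr4a1 overexpression and EGCG. Hypoxia-inducible and glycolytic genes lay near control. Of 15 hypoxia-inducible genes, 1 was higher, Kdm3a (21.9 ± 0.157 and 30.3 ± 3.55 TPM; SD, n = 3 each), and 1 lower, Egln1 (29.4 ± 1.43 and 21.2 ± 1.15 TPM), with 3 changed adjusted over the list alone. The list's median was 0.00, with a mean of -0.02, a direction of camera that was down (Benjamini-Hochberg adjusted p = 0.873) and a median of -0.01 with median-ratio scaling. Bnip3 was at 366.7 ± 8.17 and 389.7 ± 18.3 TPM (limma, Benjamini-Hochberg adjusted p = 0.832). Of 19 glycolysis genes, 4 were higher and 3 lower (median 0.09; camera, Benjamini-Hochberg adjusted p = 0.861), 8 adjusted over the list alone. Cell cycle genes were higher in 7 of 37 cases and lower in 2 (camera, Benjamini-Hochberg adjusted p = 0.634), chaperone genes higher in 6 of 28 and lower in none (0.213), proteasome genes higher in 3 of 31 and lower in 1 (0.881), and nuclear oxidative phosphorylation genes higher in 9 of 40 and lower in 2 (0.413); adjusted over the list alone, 10, 6, 3 and 19 changed.

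Beta cell transcription factors and mitochondrially encoded genes were lower than in control. Of 15 transcription factors, 8 were lower and 1 higher (median -0.31; camera, Benjamini-Hochberg adjusted p = 0.000628, and adjusted p = 0.457 with an estimated correlation), 9 adjusted over the list alone. Mafa, which drives insulin transcription, was at 62.9 ± 5.17 TPM in control and 33.3 ± 4.42 TPM with EGCG, Nkx6-1 at 4.73 ± 0.578 and 2.46 ± 0.480 TPM, Foxa2 at 17.5 ± 1.5 and 11 ± 1.37 TPM, and Neurod1 at 16.2 ± 1.70 and 11.6 ± 0.699 TPM. Mitochondrially encoded genes were lower in 9 of 13 cases and higher in none (median -0.83; camera, Benjamini-Hochberg adjusted p = 1.49e-06, and adjusted p = 0.296 with an estimated correlation), 9 adjusted over the list alone, with mt-Nd2 at 1297 ± 218 and 520.7 ± 75.7 TPM. Here too the chemoreceptor genes summed to between 50.0 and 107.7 TPM in the control libraries and to at most 11.8 TPM with EGCG. Immediate early genes were lower in 6 of 15 cases and higher in none (median -0.17; camera, Benjamini-Hochberg adjusted p = 0.0113, and adjusted p = 0.269 with an estimated correlation), 8 adjusted over the list alone, with Jun at 8.82 ± 0.892 and 5.55 ± 0.123 TPM and Jund at 34.7 ± 0.273 and 20.4 ± 3.18 TPM. Cholesterol synthesis genes were higher in 7 of 26 cases and lower in 1 (median 0.12; camera, Benjamini-Hochberg adjusted p = 0.0131, and adjusted p = 0.296 with an estimated correlation), 10 adjusted over the list alone, with Srebf2 at 7.71 ± 0.150 and 9.91 ± 0.373 TPM. The integrated stress response list was just called (8 of 26 lower and 2 higher; camera, Benjamini-Hochberg adjusted p = 0.0485, and adjusted p = 0.599 with an estimated correlation), 12 adjusted over the list alone; its median of -0.08 turned to 0.02 after rescaling, where its adjusted p was 0.0978. That call also ended when single libraries were left out, with an adjusted p of 0.204 without replicate 3 of control, 0.0590 without replicate 1 and 0.156 without replicate 3 of the EGCG group, and 0.0545, 0.0526 and 0.0540 without replicates 1, 2 and 3 of the overexpression group. Over all alternatives with camera its adjusted p was at most 0.659, without a filter on low values. Of 36 genes of the insulin granule and secretion, 6 were higher and 5 lower (camera, Benjamini-Hochberg adjusted p = 0.989), 13 adjusted over the list alone; the glucose transporter Slc2a2 was at 1.07 ± 0.312 and 3.14 ± 0.535 TPM and chromogranin A (Chga) at 1114 ± 40.3 and 793.3 ± 43.4 TPM. Ins1 did not pass the test, at 784.9 ± 45.1 and 724.4 ± 17.9 TPM.

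In the EGCG group 2172 of 11950 tested genes differed from control (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05), 1323 higher and 849 lower, of which 42 and 33 by at least 2-fold. The groups did not overlap in 34.78% of genes, where chance gives 10%. The split was 1188 higher and 1167 lower with median-ratio scaling, 1212 and 1204 with quantile normalization, and 3004 and 577 after rescaling without mitochondrial genes, small RNAs, Nr4a1 and the 10 most abundant genes; on nuclear protein-coding genes alone, added after the data were seen, it was 2280 and 716. Without the filter on low values 4775 genes were called, 1212 higher and 3563 lower. The count hung on single libraries. It was 988 without replicate 1 and 974 without replicate 2 of control, 735 without replicate 1 and 1246 without replicate 2 of the EGCG group, and 895 when the overexpression libraries were left out of the fit; without replicate 3 of control, 1512 genes were lower in place of 849. Subtracting the mean TPM of the chemoreceptor genes from every gene in each library, added after the data were seen, gave 2264 genes here, 7139 for overexpression against control and 6333 for EGCG against overexpression. At most 0.0728 TPM was subtracted, from genes that passed a filter at 1 TPM, so the counts could move little. The same amount was taken from every gene, so a greater background over repeats or mitochondrial genes was not tested.

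**Figure D3:**
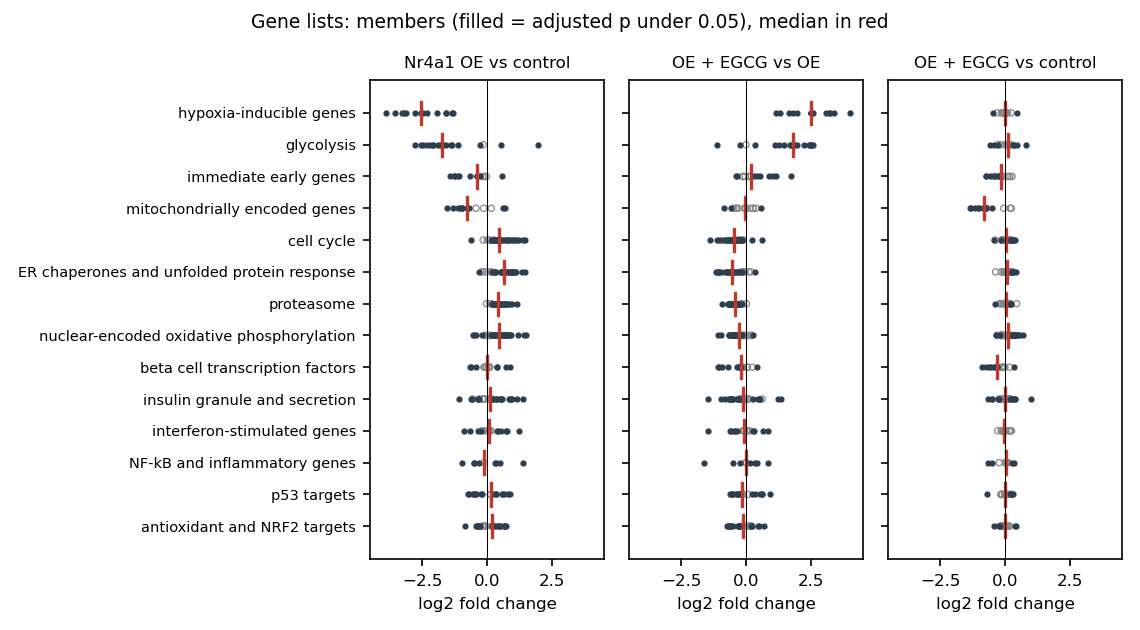
Log2 fold change of the tested members of 14 gene lists in each of the 3 comparisons (filled points have an adjusted p under 0.05, limma with Benjamini-Hochberg adjustment; red lines are medians). The median of the hypoxia-inducible genes was -2.54 with overexpression, 2.51 with EGCG against overexpression and 0.00 with EGCG against control, while that of the mitochondrially encoded genes was -0.77, -0.07 and -0.83.

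Few markers of other cell types passed the filter on low values. With overexpression, 2 of 5 duct markers rose and 1 fell, with Spp1 at 21.7 ± 1.33 and 71.4 ± 2.10 TPM and Epcam, an adhesion molecule of epithelial cells, at 20.9 ± 1.61 and 5.75 ± 0.538 TPM (SD, n = 3 each). With EGCG, Spp1 was at 29.3 ± 0.147 TPM and Epcam at 18.8 ± 1.10 TPM. The duct list was not called (camera, Benjamini-Hochberg adjusted p = 0.989), with 4 members changed adjusted over the list alone. The single tested macrophage marker, C1qa, was at 1.51 ± 0.212, 3.22 ± 0.246 and 1.5 ± 0.480 TPM in the 3 groups, and the single mesenchymal marker, Fn1, at 4.98 ± 0.806, 3.06 ± 0.166 and 3.52 ± 0.457 TPM. The endothelial markers Esam and Plvap rose and fell with overexpression, by 0.54 and -0.39 on the log2 scale, and of 2 acinar markers Bhlha15 rose (0.67) while Cela1 was at 4.68 ± 0.773 and 4.26 ± 0.449 TPM. Among 11 transcripts that follow RNA quality or are small and structured, 5 rose and 3 fell with overexpression, and 8 changed adjusted over the list alone. Their median was -0.08 and their mean 0.11, and the median was 0.08 with quantile normalization (camera, Benjamini-Hochberg adjusted p = 0.881). The nuclear transcript Malat1 was at 1056 ± 221, 414.8 ± 8.49 and 719.4 ± 182 TPM and Snora73a at 383.9 ± 88.3, 833.3 ± 49.8 and 712.6 ± 123 TPM.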

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

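The tests of Nr4a1 amount and of the TPM scale were chosen only after the results they weigh were seen, and the other tests were chosen before the values they measure were seen, except that 3 conditions, noted with Tfrc, with the chemoreceptor genes and with the transcript named next, were added after. The transcript ENSMUST00020182758, whose identifier matched no gene and so enters no comparison of genes, shares all its values with 3 other unmatched identifiers and counts with them as a single signal. It was higher with overexpression than in control (61.1 ± 52.9 and 563.4 ± 30.8 TPM, SD, n = 3 each; log2 fold change 3.57 ± 0.618 SE; limma over unmatched identifiers, Benjamini-Hochberg adjusted p = 0.00525). It was at 278.4 ± 92.1 TPM with EGCG. It was singled out because it is a signal outside the main measurement that lies above the control libraries, under the added condition that every control library is above 0. Of 219 unmatched identifiers tested, 54 were higher and 28 lower with overexpression, and 14 repeat the values of another identifier.

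The other splits of the libraries into 3 against 3 number 10 with the real one, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real count was 7106 for overexpression against control and the highest other split gave 1; for EGCG against overexpression these were 6330 and 2, and for EGCG against control 2172 and 4.

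Hypoxia-inducible genes were low with overexpression and back at control with EGCG. The tables argue against a response in proportion to the amount of Nr4a1 transcript. The lower quartile over the 15 genes of the share of the log2 change undone was 0.974. For Nr4a1 itself, the share of the rise absent in the EGCG group was 0.615 in TPM and 0.212 on the same log2 scale. Whether EGCG or a difference in transfection lowered Nr4a1 was not tested. A steep threshold between the 2 Nr4a1 levels stays open. The tables argue also against a shift of the TPM scale, since the list's median stayed at -2.65 or lower under 3 other scalings. Iron deprivation by EGCG, a candidate explanation because it raises such genes, stays open: Tfrc, whose transcript is stabilised when iron is short, was above control with EGCG (log2 fold change 0.595, 95% interval 0.477 to 0.713), which met the value set beforehand, but that value took no account of the still higher level without EGCG (14.1, 33.2 and 21.9 TPM in the 3 groups), so the added condition, a rise of Tfrc from overexpression to EGCG, was not met. Differences in oxygen or cell density between dishes, transfection itself, Nr4a1 and EGCG were not told apart by the design, and Hif1a was at 16.6 ± 1.31, 16.1 ± 0.370 and 15.5 ± 0.130 TPM.

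Of 147 small RNA genes, a group chosen after values were seen, 64 were higher, 4 lower and 79 did not pass with overexpression against control (median log2 fold change 1.02), and with EGCG 39 were higher and 0 lower than in control (median 0.791). Over 83 small nucleolar RNAs inside a tested gene, the Spearman rho across genes between their change and the host's was 0.006 (95% bootstrap interval -0.224 to 0.242). The medians were 1.18 for the RNAs and 0.15 for the hosts. For these RNAs the values argue against a rise in step with the hosts' transcript level. Transcription of the hosts was not measured and stays open. Noise in the small nucleolar RNA values, of which 55 of 98 did not pass, also draws rho towards 0. Selection of short RNAs by length could not be settled, with a rho of -0.197 between gene length and change (95% interval -0.353 to -0.026); genes are not independent replicates in either test. Recovery of small RNAs that differed between extractions, transfection and Nr4a1 itself stay open and were not tested.

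Gm10800 and 7 related satellite-like genes were high in the control libraries and fell by a median of 4.74 on the log2 scale with overexpression. Genomic DNA carried into the control libraries is a candidate source that stays open: the summed TPM of 1478 chemoreceptor genes was 11.879 times as high in control as in the mean of the 6 other libraries, and between 1152 and 1245 of these genes were above 0 in the control libraries, against 175 to 196 with overexpression and 379 to 489 with EGCG. The ratio, with every control library above all 6 others, met the value set beforehand for genomic DNA. However, these genes were chosen when the low-level signal was already known to be higher in control. Over 9800 protein-coding genes under the filter, its median was 0.0633 TPM in control and 0 with overexpression. A condition added after values were seen, that this was not so beforehand, was not met. The explanation was therefore left open. Over the 1478 chemoreceptor genes the mean was at most 0.0728 TPM in a control library. That mean does not bound the signal over single genes, since Gm10800 averaged 3872 TPM in control and 97.4 with overexpression. Transcription of such regions in untransfected cells was not tested and stays open, as does the share of the higher mitochondrially encoded signal in control that DNA could bring.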

How the results depend on the processing

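The tests on nuclear protein-coding genes alone and with subtraction of the chemoreceptor signal were chosen after results were seen. Of the values of named genes under the alternatives, 7820 stayed on their side of the threshold with the same direction, 304 lost their call, 16 gained one and 0 reversed. Of the values of lists, 1912 stayed, 39 lost their call, 115 gained one and 7 reversed. Of the counts and the log2 fold changes of Nr4a1, 272 values stayed, the counts within 1.5 times and Nr4a1 in its direction and call, and 45 counts moved. The size for Nr4a1 hung on the pseudocount: with 0.1 and 5 in place of 1 its log2 fold change was 7.389 and 4.638 for overexpression against control and 6.03 and 3.355 for EGCG against control. Without a filter on low values, 12395 genes were called for overexpression against control, 7798 of them lower, and 4775 for EGCG against control, 3563 of them lower, with 44 list tests called in place of 21; more genes were tested there, and the 9800 protein-coding genes under the filter had a median of 0.0633 TPM in control and 0 with overexpression. There 3 lists were called for overexpression against control in the direction opposite to the main fit, where camera's direction was down. They were antioxidant (median 0.158), interferon-stimulated (0.003) and ribosomal (0.109) genes (camera, Benjamini-Hochberg adjusted p = 0.0207, 0.0304 and 0.0052). The median of all genes was -0.0462 there, and the cause was not tested. With a filter at 5 TPM fewer genes were tested, and 1547 were lower with overexpression and 1303 higher with EGCG against it. With a minimum of 1 on the log2 scale the counts were by construction lower: 564 (321 higher, 243 lower) for overexpression against control, 364 (194 and 170) for EGCG against overexpression, 75 (42 and 33) for EGCG against control and 272 in opposite directions.

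For EGCG against control the count was 3581, 3004 of them higher, after rescaling, and 2280 were higher on nuclear protein-coding genes; on those genes 3704 were higher and 2696 lower with EGCG against overexpression, and the cause was not tested. With only both groups in the fit, 895 differed in EGCG against control (543 higher, 352 lower), where the full fit gave 2172. The same restriction gave 6907 for overexpression against control and 6797 for EGCG against overexpression. By at least 2-fold, 321 genes rose and 243 fell in the former and 194 and 170 in the latter, against 42 and 33 for EGCG against control. Larger changes keep their calls more easily, so whether fewer samples account for the drop cannot be told. The count of 2172 rests in part on the overexpression libraries (r of 0.984 to 0.986 within their group, against 0.972 to 0.977 within control). Their small spread and their number were not told apart. With library weights 1503 were lower, of which the cause was not tested. Leaving out each library in turn gave 735 to 3239 genes for EGCG against control, 462 to 1727 of them higher and 273 to 1512 lower. Where a group was left with 2 libraries the spread was pooled over all groups. The replicate numbers were not taken to pair the libraries, for which every pair would need a correlation of deviations over 0.1: 3 of 9 same-number pairs were over it (range -0.021 to 0.214), although 7 of 9 libraries correlated best with their own number. With the number as a replicate block 6723, 5882 and 1221 genes were called in the comparisons in the order of the report, and the last had 735 higher and 486 lower. Of 87 list tests, 0 were called by camera with an estimated correlation, 55 by fry for a direction and 81 by fry for change either way. Fry tests no contrast with other genes, so its direction differed from camera's for p53 (0.125), antioxidant (0.182) and interferon-stimulated (0.079) genes with overexpression and for NF-kB genes (-0.007) with EGCG against overexpression. Depth is unknown, so what it limits could not be given.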

Other observations

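The histone genes, the neighbours of Il4 and their measures were chosen after values were seen, and the lists were not. Lipid genes moved with overexpression in both directions. Of 16 fatty acid synthesis genes, 5 rose and 5 fell; the desaturases Scd2 (250.1 ± 6.92 to 74.9 ± 1.97 TPM, SD, n = 3 each) and Scd1 (30.2 ± 0.800 to 14.9 ± 0.825 TPM) fell, and both rose again with EGCG, to 220.5 ± 8.73 and 39.6 ± 1.57 TPM. Of 26 cholesterol synthesis genes, 12 rose and 5 fell with overexpression, with Acat2 and Mvd both up by 0.93. Of 27 autophagy and lysosome genes 11 rose and 6 fell, Sqstm1 going from 92.5 ± 3.82 to 172.0 ± 6.97 TPM. Heat shock genes rose in 7 of 14 cases and fell in 2, with Hspa8 at 243.2 ± 13.2 and 469.6 ± 45.5 TPM. Among 11 metal and iron genes, 6 rose and 2 fell, the metallothioneins Mt1 (561.4 ± 39.1 to 287.9 ± 12.6 TPM) and Mt2 (404.6 ± 24.7 to 263.4 ± 8.99 TPM). Antioxidant genes rose in 12 of 26 cases and fell in 6, with Srxn1 up by 0.72 and Me1 down from 28.9 ± 1.09 to 15.6 ± 1.46 TPM. None of these lists was called by camera for overexpression against control (Benjamini-Hochberg adjusted p between 0.510 and 0.998); adjusted over the list alone, 10, 18, 17, 9, 8 and 21 members changed in the order given.

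Members of the stress and immune lists moved both ways. Of 18 p53 targets, 8 rose and 8 fell with overexpression, with Aen up by 0.87 and Bbc3, which promotes cell death, down from 4.58 ± 0.215 to 2.33 ± 0.0513 TPM (SD, n = 3 each); of 22 genes of the BCL2 family and caspases 7 rose and 4 fell. Of 16 interferon-stimulated genes, 6 rose and 4 fell, with the chemokine Cxcl10 at 1.12 ± 0.157, 3.88 ± 0.350 and 0.740 ± 0.0985 TPM in control, overexpression and EGCG. Of 9 NF-kB and inflammatory genes 4 rose and 4 fell, with Csf1 at 9.92 ± 0.735, 27.5 ± 0.616 and 8.38 ± 1.23 TPM. Of 7 glucose-responsive genes 3 rose and 1 fell, of 3 Wnt targets none changed, of 6 disallowed and dedifferentiation genes 2 rose and 3 fell, and of 19 genes linked to Nr4a1 by earlier work 10 rose and 5 fell, with Fbp2 at 158.4 ± 1.3, 89.8 ± 3.73 and 190.3 ± 3.14 TPM. Of 80 ribosomal protein genes 32 rose and 20 fell. Adjusted over the list alone, 17, 11, 10, 8, 4, 0, 5, 15 and 52 members changed in the order given, and no list was called by camera (Benjamini-Hochberg adjusted p between 0.314 and 0.989). Medians were above 0 while camera, which compares a list with all other genes, had the direction down for p53 targets, BCL2 genes, antioxidant, interferon-stimulated, fatty acid and ribosomal genes. Median and mean differed in sign for fatty acid, glucose-responsive and NF-kB genes and for the beta cell transcription factors. With EGCG against overexpression the median and camera's direction differed for genes linked to Nr4a1, NF-kB, autophagy and ribosomal genes and transcripts of RNA quality, and the median and mean of BCL2 genes differed in sign. With EGCG against control they differed for p53, BCL2, disallowed, NF-kB, Wnt and duct genes, and median and mean for other islet hormones and transcripts of RNA quality. No list named here for a difference was called.

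Il4 is a cytokine of lymphocytes, and its rise to 15.0 ± 1.56 TPM with overexpression and return to 0.923 ± 0.205 TPM with EGCG stood beside other levels in its neighbours in the genome. Il13 averaged 0 TPM in each group, and Il5 averaged 0.02 TPM in control and 0 in the other groups. Kif3a was at 8.56 ± 2.07, 6.63 ± 0.360 and 6.40 ± 0.850 TPM and Rad50 at 9.45 ± 1.23, 8.68 ± 0.370 and 7.74 ± 0.140 TPM in the 3 groups (SD, n = 3 each). Replication-dependent histone genes summed to 8877 ± 333 TPM in control, 10659 ± 651 TPM with overexpression and 7199 ± 1306 TPM with EGCG; 30 of 63 rose and 7 fell with overexpression, and 38 fell and 3 rose with EGCG. Replicate 3 of the EGCG group was lowest at 5731 TPM. These genes share near-identical copies, and library kits for total RNA also read their unpolyadenylated transcripts.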
